A study of Homo sapiens with 3 samples.

How the data were processed

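The series holds 3 libraries of HUES8-derived SC-alpha cells, which the labels put in 1 group and number as replicates 1 to 3. The deposited matrices hold raw UMI counts per gene and barcode, with no normalization, made by the authors with Cell Ranger 4.0.0 against GRCh38 from 10x Genomics 3' v3 libraries per the labels and file headers. The gene annotation version and the cell-calling settings are not given in the sources used here; the lowest count of any barcode was 500, 503 and 501 UMIs. Each matrix has 33538 features, of which 33456 were found by gene identifier in a GRCh38 annotation used here for positions; 48 features share a symbol with another.

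Barcodes were kept with at least 1000 genes and at most 20% of UMIs from mitochondrial genes. In replicates 1, 2 and 3, 951, 1236 and 1799 barcodes fell under the gene minimum and a further 739, 313 and 992 over the mitochondrial limit. Of 3653 barcodes that passed, Scrublet, run per library with an expected doublet rate of 0.8% per 1000 cells, removed 14, 20 and 13 (47, or 1.29%), leaving 3606. For clustering, 2000 variable genes were taken without mitochondrial, ribosomal, Y-linked and XIST genes and without the function list genes found by symbol. IGF2, a member of the fetal or immature list whose symbol has 2 identifiers here, was not matched by symbol, so 1 of its identifiers entered the clustering and the list was tested without it; this was found late, and clustering without it is among the alternatives. Values were standardised within each library, and 30 principal components, 20 exact nearest neighbours and Leiden resolution 1.0 gave 15 clusters. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

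Clusters were named from 16 marker lists of 133 genes, for islet cell types, progenitors, other gut and liver lineages, mesenchyme, endothelium, pluripotent and neural cells and proliferation. A name needed a mean scaled marker score of at least 0.5, at least 3 markers at 20 CPM or more and a pseudocount of 10 CPM in the score. It was not given where the median UMI count was under 1/3 of the library median with none of the class's markers among the 10 leading genes, or where the 10 leading genes held more markers of another class. Clusters 2 to 6 were named alpha-like, 8 and 15 enterochromaffin-like, 9 neural-like and 13 proliferating.

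For the fits, counts were summed per library and class where each class had at least 20 cells in each library. Both sums of a pair come from the same library, so the library was the block of every fit (3 against 3 sums, n = 3). The test was edgeR 4.0.16 quasi-likelihood with TMM factors and filterByExpr in R 4.3.3, at a Benjamini-Hochberg adjusted p of 0.05; the SE is the log2 fold change divided by the square root of the test's F. The lists were tested two-sided with limma 3.58.1 camera, on log CPM with a prior count of 2. Its correlation was preset at 0.01 or estimated, and fry was run as a further planned test. A list counts as passed at an adjusted p under 0.05 by camera with the preset correlation. The 16 function lists hold 263 genes, of which 261 were found by symbol: islet hormones, prohormone processing, secretory granule, exocytosis, ion channels, glucose transport and glycolysis, oxidative phosphorylation, amino acid transport, islet receptors, endocrine transcription factors, unfolded protein response, immediate early and heat shock, antigen presentation and interferon, cytokine receptors, fetal or immature, and cholesterol synthesis. INS was left out of the INS comparison and GCG out of the GCG comparison. For thinning, each cell was drawn down to 5000 UMIs and cells with fewer were left out, which left 205, 199 and 236 cells on each side of the INS and GCG comparisons.

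Named genes are all islet hormones, up to 4 members per list with the largest change past the threshold, and up to 8 genes per direction outside the lists with at least 50 CPM, an absolute log2 fold change of at least 1, one sign in all 3 libraries and no use in clustering or naming. CPE against enterochromaffin-like cells, SCGN in the INS comparison, CHGA between the libraries and the cell-class levels of TTR and IRX2 lie outside that rule and were chosen after their values were seen. Some genes that the rule admits are not reported here. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only; a count of 0 is taken to allow up to 3 counts.

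The lists, groups, tests, filters, named-gene rule and most alternatives were fixed before the data were examined. The details of the cluster-naming rule, the comparison of cluster 1 with alpha-like cells, the comparison of clusters 1 to 6 and the alternatives named in the closing section as added were chosen after. The planned comparisons with beta-like, delta-like and other endocrine classes were not run, since no such class had 20 cells in each library. In counts simulated from each fit with 200 changed genes, the edgeR test recovered 48% of changes of 1 and 90% of changes of 2 on the log2 scale against enterochromaffin-like cells, 84% and 99% in the INS comparison, 88% and 99% in the GCG comparison and 92% and 100% for cluster 1, with 3, 6, 10 and 18 false calls. The 6-cluster model recovered 81.9% of changes of 1 with 9 false calls. Alternatives were DESeq2 1.42.0 size factors and its Wald test, no low-count filter, no library block, hormones left out of library sizes, each replicate left out, other filters and resolutions, all genes allowed in clustering, libraries clustered alone, a split at the median in place of the highest and lowest ranges, and thinning.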

Results

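Single-cell RNA was measured in islet-like clusters made from HUES8, an established human embryonic stem cell line, by a published protocol for stem-cell-derived alpha cells (SC-alpha cells). Alpha cells are the islet cells that secrete glucagon. The series has 1 group of 3 replicate libraries, and no second condition was analysed here, so every comparison lies within libraries. Replicates 1, 2 and 3 held 30139788, 31122791 and 30980799 UMIs (counted RNA molecules) in 2850, 2576 and 4257 barcodes. After filtering, 1146, 1007 and 1453 cells were kept, with medians of 15197, 20584 and 9966 UMIs and 3926.5, 4607 and 3067 genes. Nothing in the labels says whether the replicates came from separate differentiations. The p-values thus measure only how far differences within libraries vary between these libraries, a spread that may be technical. They do not account for groups formed by clustering or ranking the same cells.

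Alpha-like cells were the largest named class in each library. They were 55.5% ± 4.18 (SD, n = 3) of kept cells, or 622, 606 and 757 cells, with exact Clopper-Pearson 95% intervals of 51.3 to 57.2%, 57.1 to 63.2% and 49.5 to 54.7%. Cluster 1, a further 22.5% ± 3.67, scored highest on the alpha-cell markers too, but its leading genes included AFP, APOA1 and APOC3, which belong to the hepatic marker list, and it received no name. All other kept cells together carried these genes too, at lower levels. AFP stood at 274 CPM in cluster 1 against 77.9 in those cells, APOA1 at 269 against 121 and APOC3 at 513 against 261. Alpha-like cells and cluster 1 together were 78.0% ± 2.12. Enterochromaffin-like cells, which carry TPH1, the first enzyme of serotonin synthesis, were 4.60% ± 2.24, or 42, 30 and 104 cells. Neural-like cells were 2.48% ± 2.35 and proliferating cells 1.51% ± 0.206 at the chosen settings. No cluster was named neural-like at Leiden resolution 0.5, with a mitochondrial limit of 30 percent or with each library clustered on its own. Proliferating cells were 3.32%, 1.89% and 6.74% of replicates 1, 2 and 3 at resolution 0.5, 3.17%, 1.63% and 4.98% with the 30 percent limit and 0, 0 and 5.37% with libraries clustered alone. The class leaves out cycling cells elsewhere: 8 of 23, 2 of 4 and 17 of 73 neural-like cells had at least 3 of 8 cycling genes. Cluster 10, led by KRT17, MGP and COL1A1, was 2.41% ± 2.32, and cluster 14, led by ALB and AMBP, 1.40% ± 0.557; neither was named. Clusters 7, 11 and 12 were left unnamed for low UMI counts and made up 5.38% ± 5.93, 2.37% ± 0.401 and 1.88% ± 2.48. Cluster 7 was 12.02% of replicate 2 and 0.619% of replicate 3. No cluster was named beta-like or delta-like; names go to whole clusters, so this sets no limit on single cells of those kinds. With each library clustered on its own, 39 cells of replicate 2 formed a beta-like cluster and that library had no enterochromaffin-like cluster. With at least 2000 genes and at most 10% mitochondrial UMIs, 60, 42 and 135 cells were left; the alpha-like share was 32.4% ± 19.8, the enterochromaffin-like share 0 and the proliferating share 33.3%, 4.76% and 11.9%. The alpha-like share of replicates 1, 2 and 3 was 44.6%, 53.6% and 44.7% at resolution 0.5 and 40.7%, 40.02% and 43.9% at resolution 2.0. It was 45.0%, 43.4% and 43.9% with all genes allowed in clustering, 40.5%, 46.8% and 36.9% with a mitochondrial limit of 30 percent, 51.2%, 36.5% and 57.1% with doublets kept, and 49.4%, 64.9% and 52.9% with libraries clustered alone. With IGF2 also left out of clustering it was 54.6%, 59.8% and 53.4%. A share above 50% in every library thus holds at the chosen settings and in the last of these alternatives only.

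**Figure D1:**
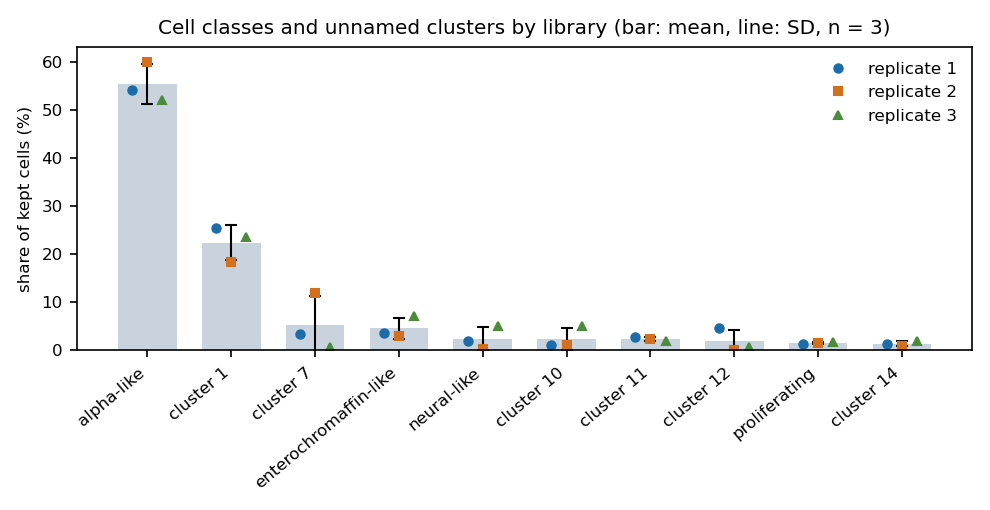
Share of kept cells (%) in each named class and unnamed cluster; bars give the mean of 3 libraries, vertical lines the SD and symbols the libraries. Alpha-like cells lie between 52.1% and 60.2%, and cluster 7 between 0.619% and 12.02%.

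The question behind the hormone values is which islet hormones SC-alpha cells transcribe. GCG, which encodes glucagon, was the highest of the 3 hormones shown by library, at 146779 ± 17317 CPM (UMIs of a gene scaled to 1e6 UMIs per sum; SD, n = 3) in alpha-like cells. TTR, a thyroid hormone carrier abundant in alpha cells, reached 72799 ± 493, and the alpha-cell transcription factor IRX2 reached 421 ± 27.6. Both are on the marker list that named the alpha-like clusters and were used in clustering, so their levels are no separate evidence for the name. INS (insulin) reached 2315 ± 1242 and SST (somatostatin) 2937 ± 1324 CPM in the same cells, against 25.4 ± 16.4 and 108 ± 82.5 in clusters 9 and 10, which carry neural and collagen genes and should lack both. IAPP (amylin) stood at 82.0 ± 14.97 and GHRL (ghrelin) at 55.4 ± 70.3. Cluster 1 held 108262 ± 28321 CPM of GCG, 965 ± 613 of INS and 1127 ± 764 of SST. GCG (ENSG00000115263) lies on chromosome 2 at 162142873 to 162152404, INS (ENSG00000254647) on chromosome 11 at 2159779 to 2161341 and SST (ENSG00000157005) on chromosome 3 at 187668906 to 187670399, all in GRCh38.

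INS and SST RNA was spread unevenly over the alpha-like cells. For each gene, the 5% of cells with the most UMIs of that gene were taken. They held 57.1% ± 14.4 of INS, 74.0% ± 4.98 of SST and 99.2% ± 0.90 of IAPP UMIs, against 15.1% ± 2.33 of GCG. A single cell held 45.5%, 81.0% and 85.0% of the IAPP UMIs of replicates 1, 2 and 3, and 29.8%, 2.82% and 65.2% of GHRL. The highest cell held 8.08%, 6.94% and 26.9% of INS, and 10.3%, 16.5% and 27.9% of SST. The highest INS level of a single alpha-like cell was 87522, 89439 and 135084 CPM. At least 1 INS UMI was found in 83.9% ± 18.01 of alpha-like cells and in 30.7% ± 20.1 of clusters 9 and 10; among cells with at least 5000 UMIs, each thinned to 5000, these were 72.2% ± 20.1 and 18.4% ± 15.1. SST was found in 67.1% ± 17.6 against 25.1% ± 15.3, and after thinning in 50.5% ± 10.5 against 13.8% ± 11.3. GCG was found in 100% of alpha-like cells and in 99.8% ± 0.39 of clusters 9 and 10, where its level was 1826 ± 1018 CPM. Median UMIs were 16543.5, 22459 and 10225 in alpha-like cells, 12998, 32288 and 13870 in cluster 9, and 13173, 14394 and 8487 in cluster 10. With at least 5 UMIs required, INS was found in 59.2% ± 31.5 and SST in 38.4% ± 12.5 of alpha-like cells.

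**Figure D2:**
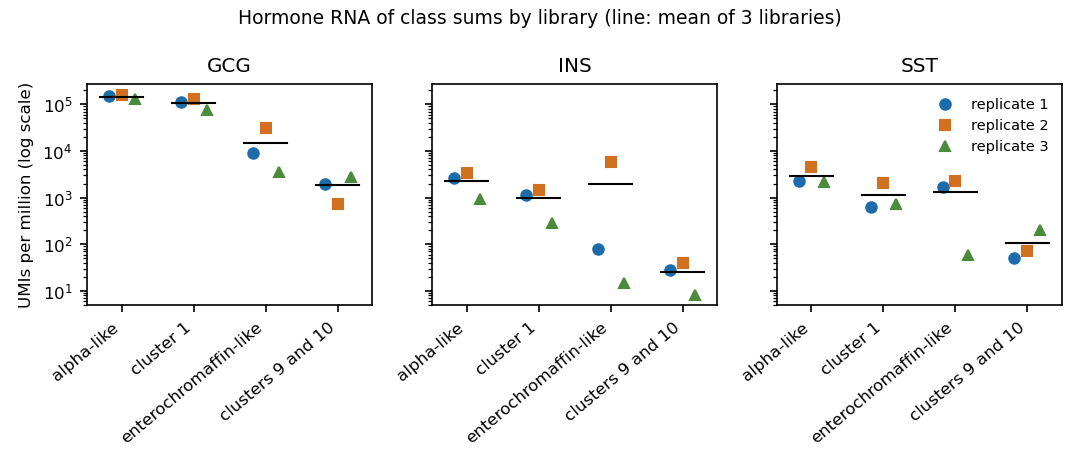
CPM (log scale) of GCG, INS and SST in the class sums of each library; symbols are libraries and lines are means of 3. INS in alpha-like cells lies at 2618, 3378 and 950, and in clusters 9 and 10 at 27.8, 40.4 and 7.95.

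Alpha-like cells were compared with enterochromaffin-like cells, the other endocrine class with enough cells, to ask what sets them apart. GCG was higher in alpha-like cells by 4.34 ± 0.31 on the log2 scale (SE, n = 3 libraries, edgeR adjusted p = 2.6e-09), with 146779 against 14499 CPM. Replicate 2 weighs most in the latter: GCG had 4793, 15634 and 2919 of 518597, 509521 and 817203 enterochromaffin-like UMIs. In each library 1 cell held much of these, at 33.3%, 29.4% and 31.1%. PCSK2, the convertase that makes glucagon, rose by 1.90 ± 0.17 and its chaperone SCG5 by 1.79 ± 0.13, while PCSK1, the other prohormone convertase, changed by -3.05 ± 0.17. The islet transcription factor ISL1 rose (2.28 ± 0.25), as did SLC7A2, a carrier of basic amino acids (2.22 ± 0.18). SYT13 (-2.97 ± 0.15), the sodium channel SCN3A (-3.16 ± 0.18) and the glutamine carrier SLC38A1 (-4.48 ± 0.22) were lower in alpha-like cells. Each of these 9 genes had its sign in all 3 libraries. In all, 1070 genes were higher and 1083 lower of 12473 tested, of which 462 and 638 differed over 2-fold. The classes come from clusters formed on some of these genes; among the 10827 tested genes not used in clustering, 863 were higher and 646 lower. The median gene's plain CPM ratio was -0.46 on the log2 scale, and fold changes are relative to it.

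The hormone list rose, with 5 higher and 0 lower of 6 tested, also adjusted over the list alone (adjusted p = 0.00798; adjusted p = 0.449 with an estimated correlation). Its median was 2.99, or 2.36 with NPY at its bound: NPY had 211 UMIs against 0 and was at least 5.35-fold higher (floor of 3 counts over the group). INS rose by 3.69 ± 0.84 but was higher in 2 of 3 libraries, and 1 cell held 94.8% of the enterochromaffin-like INS UMIs of replicate 2; without replicate 1 the change was 2.27 (adjusted p = 0.210), without replicate 2 it was 5.93 and without replicate 3 it was 2.22. SST rose by 2.29 ± 0.50, although 1 enterochromaffin-like cell held 93.5% of replicate 1's SST UMIs; the change was 1.19 without replicate 3, and its call ended without cluster 15 (2.20, adjusted p = 0.0687) and with the DESeq2 Wald test (adjusted p = 0.240). IAPP rose by 1.28 ± 0.18, and with a mitochondrial limit of 30 percent stood at -0.38. Yet IAPP was found in 5.74% ± 2.67 of alpha-like and 10.01% ± 8.91 of enterochromaffin-like cells. The enterochromaffin-like sums held 36, 28 and 19 IAPP UMIs, of which 1 cell held 83.3%, 53.6% and 89.5%. In alpha-like cells 1 cell held 45.5%, 81.0% and 85.0%, so the IAPP change rests on few cells. GHRL, at -1.31 ± 1.43, did not pass (adjusted p = 0.621); 1 cell held 98.3% of its enterochromaffin-like UMIs in replicate 1, and without that replicate it stood at 5.26 (adjusted p = 4.3e-06).

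Prohormone processing genes split, 3 higher and 3 lower of 8, with PAM, which amidates peptides, at -1.32 and the carboxypeptidase CPE at 0.88. Secretory granule genes split 7 to 4 of 11: the zinc carrier SLC30A8 rose by 2.52 and VGF by 1.40, and CHGA, a granule core protein, changed by -0.96. The CHGA call ended without replicate 3 (-0.42, adjusted p = 0.436). Of 17 exocytosis genes 2 were higher and 4 lower (3 and 5 adjusted over the list alone), with CPLX2 at -1.36 and SYT7 at 0.83. Of 20 ion channel genes 6 were higher and 5 lower (6 and 6 adjusted over the list alone), among them ABCC8 (2.15) of the ATP-sensitive potassium channel. Of 19 glucose transport and glycolysis genes 4 were higher and 1 lower, led by the glucose carrier SLC2A1 (2.07). Amino acid transport genes were 4 higher and 2 lower of 11, and islet receptors 2 and 4 of 12 (2 and 6 adjusted over the list alone), with the fatty acid receptor FFAR1 at 3.25 and the somatostatin receptor SSTR1 at -1.85. Endocrine transcription factors were 4 higher and 5 lower of 18 (5 and 6 adjusted over the list alone), with FOXA2 at -1.56.

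Oxidative phosphorylation genes rose, 8 higher and 1 lower of 30 (15 and 1 adjusted over the list alone; adjusted p = 0.0151, and adjusted p = 0.449 with an estimated correlation), among them COX6C (0.60) and COX7C (0.54). These changes are relative to the median gene: on plain CPM 4 of the 30 were higher and 26 lower in alpha-like cells (median -0.19 on the log2 scale), as were 4 and 12 of the 16 unfolded protein response genes. NDUFA4 stood at -0.49 and lost its call without replicate 1 (-0.44, adjusted p = 0.151) or replicate 3 (-0.38, adjusted p = 0.176). Unfolded protein response genes rose, 5 of 16 and 0 lower (adjusted p = 0.0438, and adjusted p = 0.449 with an estimated correlation), with CRELD2 at 0.91 and MANF at 0.80. Fetal or immature genes fell, 5 of 9 and 0 higher (6 adjusted over the list alone; adjusted p = 0.0151, and adjusted p = 0.449 with an estimated correlation), with SOX11 at -1.96 and SOX4 at -0.91 (-0.53 without replicate 2). Antigen presentation genes were 3 higher and 1 lower of 13, with HLA-B at -1.12 (-0.68 without replicate 2), and cytokine receptors 2 and 3 of 11, with IL6R at 2.34 and IL13RA1 at -3.54. The immediate early and cholesterol synthesis lists each had 0 higher and 2 lower, of 14 and 16, with HMGCS1 at -0.88. IER2 (-0.51) and JUN (-0.46) lost their calls without replicate 2 (-0.21 and -0.31). Outside the lists, SOX6 (2.81 ± 0.22), EGFL7 (2.74 ± 0.19) and GAD2, which makes GABA (2.27 ± 0.17), were the most raised genes that the naming rule admits, and UGT2B7 (-5.97 ± 0.34), ETS2 (-2.97 ± 0.29) and the retinol dehydrogenase RDH10 (-2.26 ± 0.21) the most lowered.

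The test was edgeR's quasi-likelihood test with library as block; camera's list calls numbered 4 of 16, 1 without replicate 2, 2 without replicate 3 and 0 with an estimated correlation. For the lists that passed, fry gave an unadjusted p of 0.0231 for hormones and 0.00168 for oxidative phosphorylation. It gave 0.0203 for unfolded protein response and 0.0212 for fetal or immature genes. Without replicate 1 the gene counts were 598 higher and 658 lower, and the DESeq2 Wald test gave 543 and 656. In the exocytosis list (median 0.0065, mean -0.081, test down), the ion channels (-0.068, -0.092, up), the islet receptors (-0.29, 0.070, down), the transcription factors (-0.070, 0.11, down) and the antigen presentation list (-0.096, 0.022, up), the median, mean and test differed in sign, and none of these lists passed.

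Within alpha-like cells, the third with the highest and the third with the lowest INS share of UMIs in each library were compared (INS-high and INS-low; 207, 202 and 252 cells on each side), to ask what goes with insulin RNA. SST rose by 1.83 ± 0.076 (SE, n = 3; adjusted p = 5.8e-15), from 1319 ± 124 to 4676 ± 1773 CPM, higher in 3 of 3 libraries. With all alpha-like clusters and unthinned cells, secretory granule genes rose, 5 higher and 1 lower of 11 (adjusted p = 0.0315; adjusted p = 0.469 with an estimated correlation): SLC30A8 by 0.79 ± 0.10, VGF by 0.66 ± 0.094, the granule phosphatase-like protein PTPRN by 0.47 ± 0.056 and SCG2 by 0.45 ± 0.076, with SCGN at -0.24. Exocytosis genes rose, 3 higher and 0 lower of 17 (adjusted p = 0.0326; adjusted p = 0.469 with an estimated correlation), with SYT5 at 0.57, SNAP25 at 0.36 and RAB3B at 0.32; SYT5 and SNAP25 lost their calls in several alternatives. Neither list passed in thinned cells (adjusted p = 0.0958 for both) or without cluster 5, in which granule genes stood above the other clusters of 1 to 6 (VGF by 1.77 and SCG2 by 1.48). GCG itself, at 0.19 ± 0.063, did not pass (adjusted p = 0.190), but passed without replicate 2 (0.38, adjusted p = 3.4e-14) and in thinned cells (0.12, adjusted p = 0.0260); without replicate 1 it stood at 0.048. In all 93 genes were higher and 63 lower of 11850 (47 and 14 of the 10327 not used in clustering), and 0 genes outside the lists met the naming rule.

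IAPP rose by 2.36 ± 0.28 in INS-high cells and GHRL changed by -2.93 ± 0.43, in both cases with most UMIs in few cells. Without cluster 5, which made up 16.8% ± 3.39 of INS-high and 5.05% ± 3.18 of INS-low cells, IAPP stood at -2.21 (adjusted p = 7.0e-04), and it was 3.68 without replicate 1 and 1.56 without replicate 2. Cluster 6, which carries GHRL (3.83 above the other clusters of 1 to 6) and IAPP (2.71), made up 3.52% ± 4.24 of INS-high and 18.2% ± 12.7 of INS-low cells; without it GHRL stood at -2.05 and IAPP at 2.85. Without replicate 3, GHRL stood at -0.54 (adjusted p = 0.324). NPY, at 0.20, did not pass, and stood at -0.46 without replicate 1. The hormone list, 2 higher and 1 lower of 5 (3 and 1 adjusted over the list alone), did not pass (adjusted p = 0.0743). Adjusted over the list alone, the granule list had 7 higher and 2 lower and the exocytosis list 5 and 1. Unfolded protein response genes rose, 2 of 16 and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.0315), with DNAJB9 at 0.63 and HSP90B1 at 0.27. Fetal or immature genes fell, 0 higher and 1 lower of 9 (adjusted p = 0.0315), the one gene being SOX4 (-0.42). For both of these lists too, adjusted p = 0.469 with an estimated correlation. The fry test gave an unadjusted p of 0.0719 for granule and 0.0220 for exocytosis genes. For unfolded protein response genes fry gave 0.135 and for fetal or immature genes 0.0433. Single genes of lists that did not pass were higher too: the calcium channel CACNA1A (0.46), ABCC8 (0.24), SLC7A8 (0.29), SLC3A2 (0.26), FFAR1 (0.64), the calcium-sensing receptor CASR (0.44) and CPE (0.19), with HMGCS1 at -0.33. Of 18 transcription factors 0 passed (4 higher and 1 lower adjusted over the list alone), as did 0 of 18 glycolysis and 0 of 30 oxidative phosphorylation genes. The latter lists had 0 adjusted over the list alone as well. Over all genes, 1162 had an unadjusted p under 0.05, and the DESeq2 Wald test called 10 higher and 11 lower.

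INS-high cells held 1.20, 1.01 and 1.20 times the median UMIs of INS-low cells, and 36.5% of alpha-like cells in replicate 3 had no INS UMI, so their order there was random. SYT5, SNAP25, DNAJB9, HSP90B1, CASR, FFAR1 and CPE lost their calls without replicate 2, without replicate 3, in thinned cells and without cluster 5; SYT5 stood at -0.022 in thinned cells. SCG2 lost its call without cluster 5 (0.12) and stood at 0.28 without replicate 2. Calls were also lost for VGF in thinned cells and without cluster 5 (0.40), SOX4 without replicate 3 (-0.29), SLC3A2 and ABCC8 without replicate 1 or 3, SLC7A8 without replicate 1 (0.23), CPE without any 1 replicate, and HMGCS1 without replicate 2 (-0.19). FFAR1 without replicate 2 stood at 0.52 and DNAJB9 at 0.41. The edgeR counts were 51 higher and 38 lower without replicate 3, 98 lower without replicate 2, 4 and 0 without the library block, 38 and 30 in thinned cells and 29 and 38 without cluster 5. Without cluster 6 they were 100 and 48, and SYT5 (0.49, adjusted p = 0.0538), ABCC8 and SLC7A8 lost their calls. With IGF2 also left out of clustering, 626, 602 and 776 cells were alpha-like (603, 585 and 737 of them in both) and 152 genes were higher and 143 lower; GCG passed (0.29, adjusted p = 0.00995) and SNAP25 and CASR lost their calls, so these counts turn on small changes in which cells are alpha-like. No list passed without replicate 2, in thinned cells or without cluster 5, and 1 list passed without replicate 1 and without replicate 3.

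GCG-high and GCG-low alpha-like cells, the third with the highest and the third with the lowest GCG share of UMIs, were compared in the same way, to ask what goes with glucagon RNA. GCG-high cells held 218804 ± 16577 CPM of GCG against 60966 ± 17905. The lowest GCG-low cell stood at 956, 976 and 117 CPM in replicates 1, 2 and 3. Clusters 9 and 10 held 1998, 733 and 2748, so some GCG-low cells of replicates 1 and 3 had no more GCG than those clusters. Whether cells of other kinds lie among GCG-low cells was tested only for enterochromaffin-like cells and cluster 6. PCSK1 changed by -2.47 ± 0.23 (SE, n = 3; adjusted p = 2.6e-09) and PAM by -1.12 ± 0.11, while PCSK2 rose by 0.57 ± 0.086 and SCG5 by 0.36 ± 0.056, each with its sign in 3 of 3 libraries. SLC38A1 changed by -2.02 ± 0.35, SOX11 by -1.40 ± 0.28 and SYT13 by -0.90 ± 0.15. These genes and PCSK1 had low levels. Over all alpha-like cells PCSK1 averaged 10.2 CPM, SLC38A1 3.25, SOX11 6.0 and SYT13 18.4. SLC2A1 rose by 0.58 ± 0.093, HLA-C by 0.75 ± 0.10 and SLC7A2 by 0.38 ± 0.055. In all 327 genes were higher and 198 lower of 11892 (245 and 83 of the 10368 not used in clustering), and here too 0 genes outside the lists met the naming rule. The median gene's plain CPM ratio was -0.40, so genes with smaller positive fold changes had lower plain CPM in GCG-high cells: SCG5 stood at 586 against 603.

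The other hormones fell in GCG-high cells, 4 lower and 0 higher of 5 (adjusted p = 0.00355; adjusted p = 0.744 with an estimated correlation), the same counts adjusted over the list alone. IAPP changed by -6.45 ± 0.16, SST by -1.05 ± 0.13, INS by -0.62 ± 0.11 and GHRL by -2.81 ± 0.41. With the highest cell of each sum left out, IAPP stood at -5.15, SST at -0.62 (adjusted p = 0.174) and INS at -0.28 (adjusted p = 0.127). Without replicate 3 INS stood at -0.25 and without replicate 1 at -0.95, and without replicate 2 SST stood at -0.62. GHRL was lower in 2 of 3 libraries and stood at -0.21 without replicate 3 (adjusted p = 0.715). Fetal or immature genes fell, 2 of 9 and 0 higher (3 adjusted over the list alone; adjusted p = 0.0224, and adjusted p = 0.744 with an estimated correlation): SOX11 and the neuronal microtubule protein DCX (-0.50). Oxidative phosphorylation genes rose, 4 of 30 and 0 lower (19 adjusted over the list alone; adjusted p = 1.5e-04, and adjusted p = 0.744 with an estimated correlation): UQCRB by 0.27, COX7C by 0.23, COX6C by 0.21 and NDUFB2 by 0.21. On plain CPM all 30 were lower in GCG-high cells (UQCRB at 437 against 476), and these 4 genes lost their calls without replicate 2, without replicate 3 and when ranked within each cluster. Unadjusted p by fry was 0.182 for the other hormones, 0.0180 for fetal or immature and 0.144 for oxidative phosphorylation genes.

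Among lists that did not pass, processing genes were 2 higher and 2 lower of 8 (3 and 3 adjusted over the list alone; median 0.024, mean -0.34) and granule genes 2 and 2 of 11 (3 and 3; median 0.037, mean -0.069), both tested as down. VGF, at -0.59, was lower in 2 of 3 libraries and stood at -0.23 without replicate 2 (adjusted p = 0.554). SLC30A8, at 0.42, was higher in 2 of 3 libraries and stood at 0.20 without replicate 1 (adjusted p = 0.368) and at 0.77 without replicate 2. CASR (-0.52) lost its call without replicate 2 (-0.34), and SCN3A (-0.69) without replicate 2 or 3. CALR, an endoplasmic reticulum chaperone, stood at -0.30 and HLA-E at -0.45. SNAP25 (-0.35), JUNB (0.20), HSPA1A (0.42), SYT11 (-0.33), INSIG1 (-0.27) and HMGCS1 (-0.25) each lost their call without 2 or more of the replicates taken 1 at a time, while CADPS stood at 0.31. PTPRN2, at 0.36, lost its call without replicate 2 (0.37, adjusted p = 0.0501). NPY, at 0.58, did not pass with all 3 libraries but did without replicate 3 (1.07, adjusted p = 0.0386).

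GCG-high cells held 1.40, 1.28 and 1.51 times the median UMIs of GCG-low cells. Their median mitochondrial share differed from that of GCG-low cells by -1.32, -0.49 and -1.23 percentage points. Cluster 2 was 63.2% ± 7.60 of GCG-high and 6.75% ± 6.19 of GCG-low cells, and cluster 3 was 9.61% ± 7.77 and 48.0% ± 6.89. Cluster 6 was 1.56% ± 1.59 of GCG-high and 20.5% ± 8.87 of GCG-low cells. It stood above the other clusters of 1 to 6 in PCSK1 (2.33), PAM (1.11), SLC38A1 (3.44), SOX11 (1.60), DCX (1.12), SYT13 (1.05), GHRL (3.83) and IAPP (2.71). Without it PCSK1 stood at -2.11, PAM at -0.84, SOX11 at -1.29 and SYT13 at -0.67, SLC38A1 had too few counts to be tested, DCX (-0.26, adjusted p = 0.225), SLC2A1 (0.29, adjusted p = 0.106) and SCN3A lost their calls, and 281 genes were higher and 125 lower. The edgeR counts were 152 higher and 89 lower without replicate 2, 194 higher without replicate 3, 3 and 5 without the library block, 159 and 59 in thinned cells and 42 and 68 when ranked within each cluster, with 1 list past the threshold without replicate 3 and 131 and 15 genes by the DESeq2 Wald test.

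**Figure D3:**
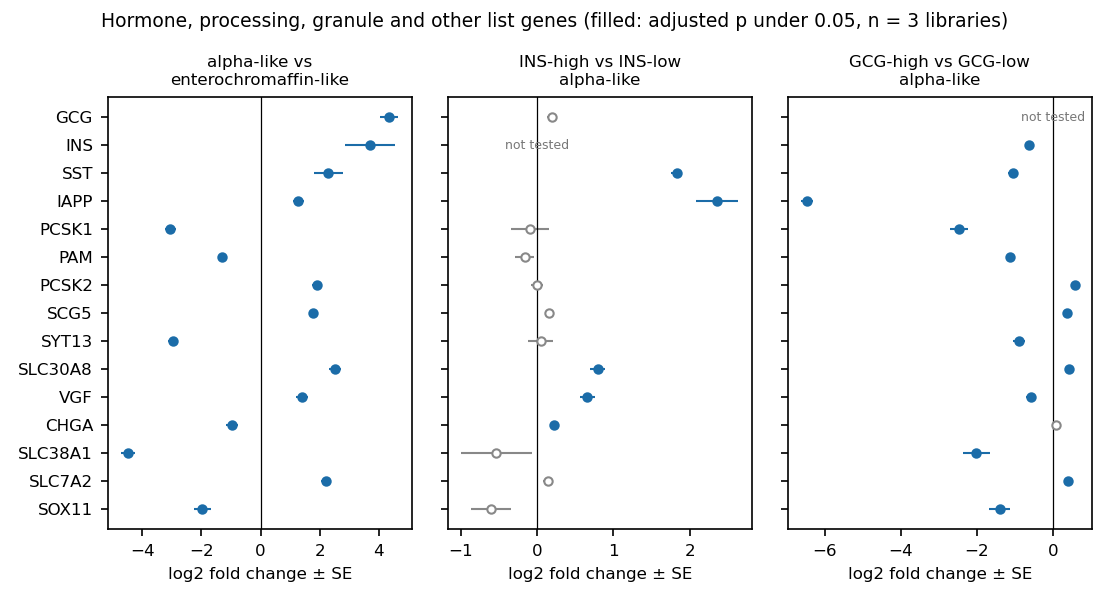
Log2 fold change ± SE of 15 genes in the 3 comparisons (n = 3 libraries); filled symbols passed at an adjusted p under 0.05. PCSK1 lies at -3.05 against enterochromaffin-like cells and at -2.47 in GCG-high cells, and open in INS-high cells.

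Between the libraries, 37 of 2641 genes at 50 CPM or more in alpha-like cells ranged over 2-fold (1.40%). They included INS (950 to 3378 CPM), SST (2105 to 4464), GHRL (12.6 to 136), CHGA (4754 to 13157) and SOX4 (63.3 to 198). Of 10 immediate early and heat shock genes at that level 6 ranged over 2-fold, namely FOS, FOSB, JUNB, EGR1, IER2 and DUSP1, and the list's median stood at 0.14, -0.60 and 0.42 on the log2 scale around the mean of libraries in replicates 1, 2 and 3. At that level, 0 of 6 prohormone processing, 0 of 28 oxidative phosphorylation and 0 of 11 unfolded protein response genes ranged over 2-fold. Lower processing genes were not counted: PCSK1 stood at 6.001, 5.532 and 19.037 CPM in replicates 1, 2 and 3, and PAM at 44.601, 41.347 and 34.389. Across genes, Pearson's r of log2 CPM between libraries was 0.974 to 0.986; genes are not independent replicates.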

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

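The tests of free RNA for insulin and somatostatin RNA, of ALB for cluster 1, of depth for the GCG comparison, of SLC38A1 alone and of other splits were chosen only after the result was seen; those of doublets and of enterochromaffin-like and cluster 6 cells in GCG-low cells were set before their values were seen, the doublet test after the UMI ratio of INS-high to INS-low cells had been read.

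Barcodes that the filters removed still held GCG above the limit that a count of 0 allows. Free RNA alone could pass that limit in pools of so many UMIs, so passing it does not show that alpha cells were removed. Among barcodes over the mitochondrial limit, GCG stood at 114375, 145165 and 89078 CPM of non-mitochondrial UMIs in replicates 1, 2 and 3. Among barcodes under the gene minimum it stood at 50076, 64661 and 30073. The reported comparisons use neither set; the alternative with a mitochondrial limit of 30 percent takes in part of the former, for 1451, 1225 and 2109 cells against 1146, 1007 and 1453.

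For insulin RNA in alpha-like cells 2 technical explanations were tested, and no biological one, since the design has 1 group. Names go to whole clusters, so single beta-like or delta-like cells within alpha-like clusters could hold part of the INS and SST RNA. That was not tested and stays open. Free RNA from lysed cells would bring INS to clusters 9 and 10 too, but INS there was at most 0.0120 times the alpha-like level over the 3 libraries. SST there was 0.0223, 0.0158 and 0.0961 times the alpha-like level. These values argue against free RNA as the main source of either in the alpha-like sums, although clusters 9 and 10 held 4 and 11 cells in replicate 2. The 5% of alpha-like cells with the most SST UMIs held 69.3%, 73.4% and 79.2% of them. The ratios therefore say less about SST in the other alpha-like cells, where free RNA stays open. Pairs of an alpha-like and an insulin cell in 1 droplet would hold more UMIs. The 5% of alpha-like cells with the highest INS share held 51.1%, 42.7% and 72.3% of INS UMIs, and at most 1.17 times the median UMIs of the other alpha-like cells (1.17, 1.07 and 1.10). That argues against such pairs of cells of similar depth as the main source; pairs with a cell of few UMIs, and single droplets with much of the INS, stay open. Doublets were not tested for SST.

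AFP and apolipoprotein RNA in cluster 1 might come from cells or RNA of the ALB-expressing kind in cluster 14. The AFP excess of cluster 1 would need an ALB excess of 528, 3746 and 1478 CPM in replicates 1, 2 and 3, and the measured excess was 1.33, 3.50 and 1.34, at most 0.00252 times the need. These values argue against cluster 14 as the source, although its levels rest on 15, 9 and 29 cells. No biological explanation was tested, as the design has 1 group.

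PCSK1, PAM, SLC38A1 and SOX11 were lower in GCG-high cells and are all higher in enterochromaffin-like cells, so such cells among the GCG-low cells could be the source. Over 72 genes at least 4-fold higher in enterochromaffin-like cells, the median share of such cells was 3.59%, 4.22% and 3.24%, against the 25.9%, 23.5% and 17.2% that the 4 genes would need (medians), a mean ratio of 0.169. The ratio was at most 0.225 for PCSK1, PAM and SOX11 in any library, which argues against such cells as the source for these 3. SLC38A1 alone would need 10.9%, 4.06% and 5.56%, a mean ratio of 0.650 (0.330, 1.04 and 0.582), so for it this explanation stays open. In thinned cells 159 of the 198 lower genes could be tested, and all 159 kept their sign, with log2 fold changes a median of 0.976 times the unthinned ones (quartiles 0.776 and 1.20). Thinning leaves a gene's expected share of each cell's UMIs as it was. The kept signs thus speak only to the number of UMIs counted per cell. Whether deeper cells differ in other ways was not tested, so depth stays open. Of the 159 genes, 51 were still called lower, with fewer counts per cell, and PCSK1 stood at -1.83 and PAM at -1.15. SLC38A1 and SOX11 were not among the 159. Cluster 6, which has all 4 genes raised (PCSK1 2.33, PAM 1.11, SLC38A1 3.44, SOX11 1.60), made up 20.5% of GCG-low and 1.56% of GCG-high cells and could be a source. Without it, the log2 fold changes of 191 of the 198 lower genes were a median of 0.877 times those with all clusters (quartiles 0.632 and 1.01), and 100 of them were still called lower; the lower genes outside these 191, SLC38A1 among them, had too few counts to be tested without it. That argues against cluster 6 as the whole cause, but a part in it stays open, as does a smaller share of enterochromaffin-like cells, and no biological explanation was tested, as the design has 1 group.

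For the comparison with enterochromaffin-like cells, 1 of 10 splits of the 6 sums (the real one, 2153 genes) gave as many genes and the highest other gave 0; for the INS comparison these were 1, 156 and 2, for the GCG comparison 1, 525 and 2, and for cluster 1 against alpha-like cells 1, 968 and 1. The 10 splits are too few for a share under 0.05. Among the 4 splits that part every pair, the highest other gave 0, 1, 0 and 0 genes; the remaining splits put both sums of a library on one side.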

How the results depend on the processing

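The mitochondrial limit of 30 percent, IGF2 left out of clustering, cluster 1 added, cluster 15, 5 or 6 left out, ranking within clusters, leaving out the highest cell of each sum and every test of cluster 1 were added after the data were seen. Of 1316 values of 78 named genes against enterochromaffin-like cells, 1255 kept direction and side of the threshold, 48 lost the call, 4 gained it and 9 turned; for the INS comparison these were 251, 102, 4 and 5 of 362, for the GCG comparison 406, 138, 1 and 1 of 546, and for cluster 1 357 and 129 of 486 with no turns. The cause was not tested, except that leaving out a library or thinning leaves fewer counts. Depth limits the small classes. In the fits as reported, 30 enterochromaffin-like cells in replicate 2 is the lowest sum, and 24 is the lowest fitted, without cluster 15. The levels in clusters 9, 10 and 14, which were not fitted, rest on 4, 11 and 9 cells in replicate 2. Beta-like, delta-like and other endocrine comparisons were not run, and the comparison with enterochromaffin-like cells was not run with libraries clustered alone or with the strict filter, which left 0 such cells; leaving out replicates was not run for the 6-cluster model.

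Turned values against enterochromaffin-like cells were GHRL at 1.81 (DESeq2 Wald test), 4.06 (resolution 0.5), 4.07 (all genes allowed in clustering), 1.54 (highest cells left out), 3.80 (30 percent limit) and 5.26 (without replicate 1; range -4.34 to 5.26 without single replicates), HLA-E at -0.077 (resolution 0.5) and -0.029 (all genes), and IAPP at -0.38 (30 percent limit). In the INS comparison IAPP was -2.21 without cluster 5, NPY -0.28 in a median split, -0.31 without cluster 6 and -0.46 to 0.65 without single replicates, and SYT5 -0.022 thinned. In the GCG comparison NPY was -0.064 to 1.07 without single replicates.

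Counts with the DESeq2 Wald test, higher and lower, were 543 and 656 against enterochromaffin-like cells (1070 and 1083 by edgeR), 10 and 11 for INS (93 and 63), 131 and 15 for GCG (327 and 198) and 125 and 69 for cluster 1 (536 and 432). With no replicate block they were 4 and 0 for INS, 3 and 5 for GCG and 8 and 6 for cluster 1. Thinned cells gave 38 and 30 for INS and 159 and 59 for GCG; ranking within clusters 44 and 32, and 42 and 68; no low-count filter 140 and 121 for INS; no cluster 5 gave 29 and 38 for INS and 507 higher for GCG; no cluster 6 gave 125 lower for GCG; IGF2 left out of clustering gave 152 and 143 for INS; a median split gave 60 higher and cluster 1 added 96 lower for INS. Without single replicates the ranges were 598 to 1188 and 658 to 1081 against enterochromaffin-like cells, 51 to 108 and 38 to 98 for INS, 152 to 259 and 89 to 144 for GCG, and 273 to 350 lower for cluster 1.

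List counts with an estimated correlation were 0 in all 4 comparisons. Against enterochromaffin-like cells (4 lists) they were 1 at resolution 0.5, and 2 with highest cells left out, hormones left out of library sizes, the 30 percent limit or without cluster 15. For INS (4) they were 2 with cluster 1 added, 1 in a median split or ranked within clusters, and 0 with no low-count filter, thinned or without cluster 5; for GCG (3), 1 with highest cells left out. Without single replicates the ranges were 1 to 4, 0 to 1, 1 to 3 and, for cluster 1 (9), 5 to 11.

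The alpha-like share (55.5%) was 47.6% at resolution 0.5, 41.5% at 2.0, 44.1% with all genes in clustering, 32.4% with the strict filter, 48.3% with doublets kept and 41.4% with the 30 percent limit. Together with cluster 1 (78.0%) it was 80.4% at resolution 0.5, 72.0% at 2.0, 32.4% with the strict filter and 73.8% clustered alone; the enterochromaffin-like share was 0 with the strict filter. With at least 5 UMIs required, cells with GCG and INS were 59.2% and with GCG and SST 38.4%.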

Other observations

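The comparisons of cluster 1 and of clusters 1 to 6 and the draws of cluster names here were all chosen after the result was seen; the draws were planned before any was run, but their number was set after a first run had been read.

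Cluster 1 against alpha-like cells had lower hormone RNA (edgeR, library as block, n = 3): INS by -1.39 ± 0.057 (SE), SST by -1.53 ± 0.062 and GCG by -0.51 ± 0.046, each lower in 3 of 3 libraries, with 6 of 6 hormones lower (adjusted p = 6.1e-07; adjusted p = 0.314 with an estimated correlation). Granule genes fell, 8 of 11 and 0 higher (adjusted p = 1.4e-04; adjusted p = 0.314 with an estimated correlation), led by SLC30A8 (-1.06 ± 0.075) and SYT13 (-0.72 ± 0.13). Cholesterol synthesis genes rose, 10 of 16 and 0 lower (14 adjusted over the list alone; adjusted p = 1.2e-05, and adjusted p = 0.382 with an estimated correlation), among them INSIG1 (0.46) and HMGCS1 (0.45). Immediate early and heat shock genes rose, 8 of 14 and 0 lower (adjusted p = 1.4e-04; adjusted p = 0.314 with an estimated correlation), with IER2 at 0.74 and JUN at 0.47. By fry the unadjusted p was 0.00981 for hormones, 8.3e-04 for granule, 0.072 for cholesterol synthesis and 0.019 for immediate early and heat shock genes. Of 12873 genes 536 were higher and 432 lower. Among the 11250 not used in clustering, 365 were higher and 244 lower.

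In a model of clusters 1 to 6 with library as a term (11085 genes), cluster 5 stood above the other 5 clusters in 26 of 30 oxidative phosphorylation genes and below in 0 (adjusted p = 3.2e-14; adjusted p = 0.135 with an estimated correlation), with UQCRH at 0.61 and COX5A at 0.56. Its granule genes were 6 higher and 0 lower of 11 (adjusted p = 9.7e-05; adjusted p = 0.0159 with an estimated correlation), with VGF at 1.77 and SCG2 at 1.48, and IAPP stood at 7.26 and INS at 2.09. Cluster 3 stood below the others in 25 of 30 oxidative phosphorylation genes and above in 0 (adjusted p = 1.3e-20; adjusted p = 0.0746 with an estimated correlation), with NDUFB9 at -0.44, and above in 5 of 18 transcription factors and below in 0 (adjusted p = 5.8e-05; adjusted p = 0.0874 with an estimated correlation), with NEUROD1 at 0.49. Cluster 5 had 1036 genes higher and 461 lower, and cluster 3 299 and 668.

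The hypothesis that random cluster names within libraries would give as many genes was tested with 60 draws of names, the real one included: 1 draw, the real one, gave as many for cluster 5 (1497 genes; highest other 6) and 1 for cluster 3 (967; highest other 51). Clusters were formed from expression in these same cells, which favours the real names from the start, so the draws decide nothing about chance. A first run with more draws was read before the number was set to 60 to limit computing time; there too the real names of clusters 3 and 5 gave the most genes, while for clusters 2 and 4 another draw gave as many.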
